A study of Mus musculus with 8 samples.

How the data were processed

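Gene expression was measured in whole cortex dissected from mouse embryos at embryonic day 12.5, with 4 control cortices and 4 cortices of Pbx1 mutants, each on 1 array of its own. Per the labels' protocols, the tissue was kept in RNAlater until the genotype was known, RNA was extracted with a Qiagen kit, and amplified RNA carrying Cy3 was hybridised to Agilent whole mouse genome arrays in 1 colour. The labels give the genotype and a mixed strain background, and give neither litter nor sex, nor whether controls carried the cre. Nothing in the labels says whether the 4 cortices of a group came from separate litters, so the p-values measure the spread between these 8 samples.

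The deposited scanner files hold intensity values per spot, as the authors' extraction with Agilent Feature Extraction wrote them. Its version is 10.7.3.1 per the file headers and 10.5 per the submitters' processing notes. The processed signal in those files is background-subtracted and spatially detrended per the file headers, with no scaling between arrays. The array's design names the mouse build mm9 per the file headers. The authors also deposited a value table on a log2 scale, which was compared with the scanner files because its making is not given in the sources used here. Each of its columns had a rank correlation of 0.999998 to 0.999999, across probes, with the median spot signal of its array, against 0.9925 to 0.9975 with the processed signal. The columns shared a maximum of 18.95 and had a median of 7.48, or 7.47 in mutant 4, so the values were scaled to a common distribution between arrays and were not centred per gene. Since the arrays have 1 colour, no direction of a ratio was left open.

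Each array held 43379 probe spots of 41174 probes, of which 245 were spotted 10 times, and 1639 control spots that were left out. Between 75% and 82.7% of the probes were well above background on an array, the 75th percentile of the processed signal lay between 2254 and 2950, and no spot was saturated. Spots that the extraction software marked as non-uniform or population outliers, 52 to 89 per array, were left out, and spots of a probe were averaged. The main measure was log2 of the processed signal minus the array's 75th percentile. Probes well above background on at least 4 of the 8 arrays were kept, whatever the group, which left 31702 probes. A gene with several probes was represented by the probe with the highest mean over the 8 arrays, which gave 24322 genes, 14739 of them with a symbol. Of these genes, 43 lacked the value of at least 1 array. Levels of different probes are not comparable with each other, and the number of arrays limits the precision.

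Probes were named through their RefSeq accession, without its version, in a RefSeq table of the assembly GRCm38.p6. A symbol was found for 24844 probes (17178 symbols), 16330 probes had none, and 0 had several. Because that assembly differs from the build of the array design, no coordinates are given, and the table served only for names and for which genes lie near each other. The probe sequences and the deleted part of Pbx1 are not given in the sources used here, so it is not known whether any Pbx1 probe lies in the deleted part. A probe outside it does not test the recombination itself.

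Mutant and control arrays were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (version 1.17.8), and figures were drawn in Python 3.11.15. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Errors of differences are the standard errors of that fit, and errors of group means are SDs over the 4 samples of a group. The median residual SD was 0.237 on the log2 scale, with 2.1 prior degrees of freedom. Gene lists, 24 in all with 341 different genes of which 306 were tested, were compared with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation was an alternative on all 8 arrays, and members were also adjusted over the list alone. List calls under the other settings used the preset correlation. A list's level on an array is the mean of its members after each gene's mean over the 8 arrays was subtracted. Exact permutation tests over the 35 splits of the 8 arrays into 4 and 4 were used for single values, and the smallest two-sided p they can give is 0.0286. Genes within 10 Mb of Pbx1 or Emx1 were compared with all other named genes by Fisher's exact test, two-sided.

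The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, per direction, up to 12 passing genes with the largest difference whose 4 mutant values all lie on one side of the 4 control values. Where fewer pass, it fills up to 6 with the smallest unadjusted p, given as not passing. It also names Pbx1, Pbx2, Pbx3 and Emx1, and from each list up to 4 members that pass or, where none passes, the 2 with the smallest p. Genes without a symbol were counted and not named by this rule, and a member named beyond this rule was chosen after its value was seen.

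The arrays came from 2 slides, each scanned separately, and each slide held 2 controls and 2 mutants. Slide 1 held controls 1 and 3 with mutants 2 and 4, and slide 2 held controls 2 and 4 with mutants 1 and 3. The alternatives were normexp background correction (offset 50) on the median spot and background signals, quantile normalization, median scaling, the deposited value table, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, every probe tested, slide as a block, each slide alone, the replicate number as a block, each array left out in turn, trended and robust eBayes, array weights, Xist as a covariate, limma's treat with a minimum fold of 1.2, an estimated correlation in camera, windows of 5 and 20 Mb, and the neighbour count without the 2 loci. The normexp alternative was planned on the mean spot signal and used the median one, since the files used here hold no mean signal. Slide block with trended and robust eBayes, position on the slide as a block, slide block with Xist, and the neighbour count at an unadjusted p were added after the data had been seen. The fit was tested on simulated data for the mutant against control comparison over 24279 genes. It recovered 59% of 100 genes shifted by 1 on the log2 scale and 78% of 100 genes shifted by 2. There were 7 false calls, and the sign was right in 100% of the recovered genes. Benjamini-Hochberg is less strict where many genes change, as in the simulation. These shares are therefore not the power of the real comparison, where far fewer genes passed. The list test, with the cell cycle list shifted by -0.5, called that list (camera adjusted p = 3.52e-31) and 0 other lists. Without the shift it called 0 lists. The simulated genes varied independently of each other, and the shift was larger than the -0.14 of the real cell cycle list. Members of that list had an estimated correlation of 0.217 in the real arrays. The simulation therefore does not show how often the list test calls lists by chance in these data.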

Results

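Whole cortex of mouse embryos at embryonic day 12.5 was profiled on 1-colour arrays in 4 controls and 4 mutants. Controls carried 1 floxed and 1 wild-type allele of Pbx1, a TALE-class homeodomain transcription factor. Mutants carried 1 floxed and 1 null allele together with a cre driven by Emx1, which is active in the progenitors of the dorsal telencephalon. The comparison asks which transcripts of the early cortex differ between these genotypes. Mutants carry the null allele outside that lineage too, and it is not known whether controls carried the cre. Effects of either cannot be told apart here from loss of Pbx1 in that lineage. On each array 75% to 82.7% of the probes were well above background, and 24322 genes were tested. Levels are log2 signals relative to the 75th percentile of the array.

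Pbx1 fell in the mutant cortex to 31% of the control level. Its brightest probe (A_51_P130203, for NM_183355) measured 2.72 ± 0.25 in controls and 1.03 ± 0.07 in mutants (SD, n = 4 each). The difference was -1.69 with a standard error of 0.13, a 3.23-fold lower level, and all 4 mutants lay below all 4 controls (limma adjusted p = 0.0307). The other 2 Pbx1 probes differed by -2.0 ± 0.21 (A_51_P413238, to 24.9% of control) and -1.93 ± 0.17 (A_52_P543460, to 26.3% of control; SE). Each of the 3 probes had an exact permutation p of 0.0286, the smallest that 4 against 4 arrays allow. Whether a probe lies in the deleted part of Pbx1 is not known. Its paralog Pbx2 differed by 0.00 ± 0.12 on its brightest probe and by -0.17 ± 0.11 on the other. Pbx3 differed by -0.20 ± 0.21 and Emx1, whose regulatory sequences drive the cre, by -0.16 ± 0.17 (SE), neither past the test. Pbx1 was lower by -1.84 within slide 1 and by -1.54 within slide 2, and the adjusted p was 0.0413 with slide as a block. The adjusted p rose above the threshold without control 1 (0.141), control 3 (0.241), control 4 (0.263), mutant 1 (0.201), mutant 2 (0.122), mutant 3 (0.129) or mutant 4 (0.27), with a difference between -1.81 and -1.62 in every left-out set.

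**Figure D1:**
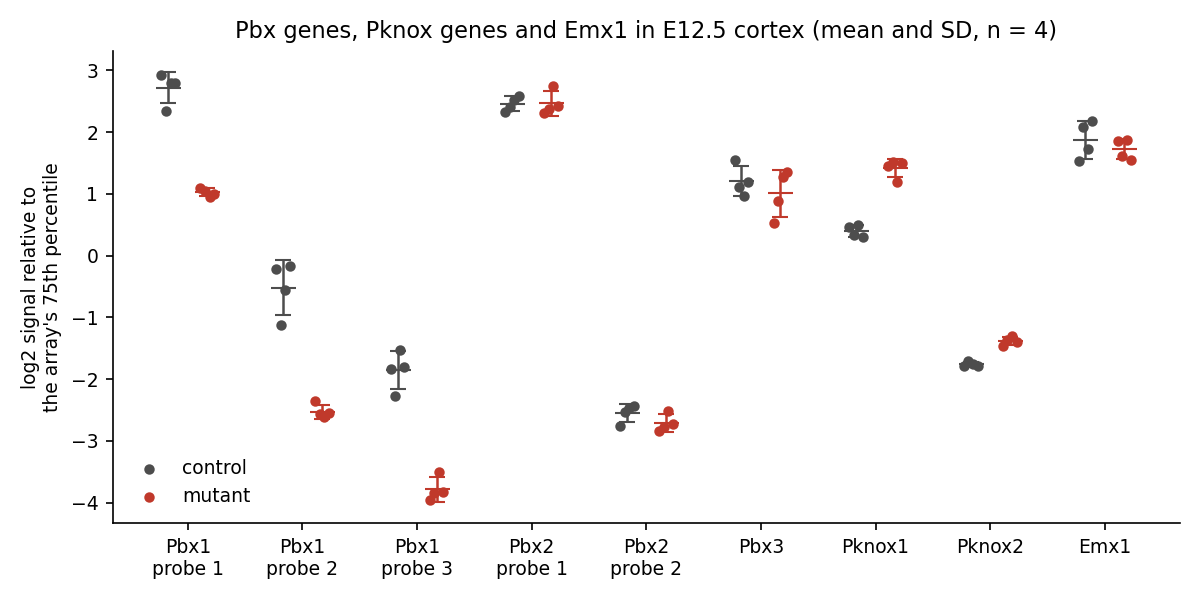
Log2 signal relative to the array's 75th percentile for the Pbx1, Pbx2, Pbx3, Pknox1, Pknox2 and Emx1 probes in 4 control (grey) and 4 mutant (red) cortices; dots are arrays, horizontal lines the means and bars the SD. The 4 mutants lie below the 4 controls on all 3 Pbx1 probes and above them for Pknox1 and Pknox2, while the groups overlap for Pbx2, Pbx3 and Emx1.

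Pbx1 was the only gene that changed over all genes tested, with 0 genes higher and 1 lower (limma). That call was lost under several other settings on all 8 arrays. Among them were quantile normalization (limma adjusted p = 0.0738), no filter on dim probes (0.0771), the deposited value table (0.0804) and Xist as a covariate (0.0823). With position on the slide or the replicate number as a block, the adjusted p of Pbx1 lay far above the threshold. At an unadjusted p under 0.05 there were 619 genes, 213 with higher and 406 with lower values in mutants, against 1216 by chance in data without further structure. With slide as a block the count was 1092. Mutant and control values did not overlap for 430 genes (1.77%). The 2.86% that chance gives holds for arrays without slide differences, and each group held arrays of both slides, so the 2 shares are not directly comparable. The gene nearest the threshold in the other direction was Pknox1, a TALE homeodomain protein that forms complexes with Pbx proteins. It measured 0.40 ± 0.10 in controls and 1.41 ± 0.15 in mutants (SD, n = 4 each), a 2.02-fold higher mean level. All 4 mutants lay above all controls, and Pknox1 did not pass (limma adjusted p = 0.13). Within slide 1 it differed by 1.02 and within slide 2 by 1.01. With slide as a block its adjusted p was 0.0413, so that 2 genes passed. The slides set the main structure of the data: 4612 genes differed between them, and the first principal component, with 39.3% of the variance, separated them.

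None of the other genes with the smallest p passed the test, and their values are given as such (SE of the difference). Among those with higher values in all 4 mutants were Adcyap1, which encodes the neuropeptide PACAP (0.88 ± 0.17), Cpne4, a calcium-dependent membrane-binding copine (0.86 ± 0.18), Lmcd1, a LIM-domain cofactor (0.61 ± 0.12), and Spaca1, known from the sperm acrosome (0.57 ± 0.12). Pknox2, the paralog of Pknox1, differed by 0.38 ± 0.08. Those with lower values in all 4 mutants were Rai14 (-1.18 ± 0.21), the guanylate cyclase subunit Gucy1b2 (-1.09 ± 0.16), the nucleolar protein Nol9 (-0.81 ± 0.11), the transporter Slc16a14 (-0.81 ± 0.15) and the secreted kinase Pkdcc (-0.78 ± 0.12). The 3 probes of Rai14 went the same way by unequal amounts, with -0.62 and -0.37 on the other 2. Their adjusted p lay between 0.465 for Nol9 and 1. After normexp background correction the differences were smaller for Nol9 (-0.50), Slc16a14 (-0.45) and Spaca1 (0.30).

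Of the 12 genes of the Pbx and TALE partner list, 1 fell (Pbx1) and 11 did not pass over all genes. Adjusted over the list alone, 3 passed: Pbx1 lower (1.51e-05), Pknox1 higher (6.44e-05) and Pknox2 higher (0.00606; limma). Meis2, a further Pbx partner, differed by 0.30 ± 0.12 and Meis1 by 0.14 ± 0.31 (SE). As a list the 12 genes were not called by camera (adjusted p = 0.121, direction higher, mean difference 0.04), with Pbx1 and the Pknox genes on opposite sides of 0. The list was called higher without mutant 1 (adjusted p = 0.0355) and after normexp background correction (0.027).

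Cell cycle genes had lower values in the mutant cortex for all 18 measured members, by -0.14 on average. The list shifted lower (camera adjusted p = 3.08e-05), and with an estimated correlation the call was lost (adjusted p = 0.465 with an estimated correlation). None of the 18 genes passed alone in limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. It was Top2a, the topoisomerase of replicating chromosomes (-0.35 ± 0.11), and the next by p were the spindle checkpoint kinase Bub1 (-0.20 ± 0.09) and the replication licensing factor Mcm2 (-0.21 ± 0.11; SE). The list's level was 0.07 ± 0.08 in controls and -0.07 ± 0.05 in mutants (SD, n = 4 each; exact permutation p = 0.0571). The groups overlapped, with control 1 at -0.03 and the mutants between -0.13 and -0.01. The mean difference was -0.11 within slide 1 (adjusted p = 0.0532) and -0.18 within slide 2 (2.86e-05), and the adjusted p was 2.12e-06 with slide as a block.

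Radial glia genes, which mark the neural progenitors of the ventricular zone, were on average not lower. Of 14 measured members 10 had higher and 4 lower values, with a mean difference of 0.07, and the list was not called (camera adjusted p = 0.187), while after normexp background correction it was called higher (0.0447). None passed in limma over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. These were the glutamate transporter Slc1a3 (0.47 ± 0.13) and the fatty acid binding protein Fabp7 (0.28 ± 0.10), while the progenitor factors Pax6 and Sox2 differed by 0.02 ± 0.17 and 0.04 ± 0.16 (SE). The intermediate progenitor and neurogenesis list, with 8 of 14 members higher and a mean of 0.02, was not called either (adjusted p = 0.413). Its named members were the neuronal differentiation factors Nhlh1 (0.23 ± 0.12) and Insm1 (0.21 ± 0.15), and Eomes, which marks intermediate progenitors, differed by -0.13 ± 0.16. None of its members passed in limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05.

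Markers of excitatory cortical neurons and of the subplate were on average higher in mutants. In the excitatory list 15 of 20 members had higher values, with a mean difference of 0.10 (camera adjusted p = 0.0376), a call that was lost with an estimated correlation (adjusted p = 0.643), and the exact permutation p of the list level was 0.4. In the subplate list, named for the earliest-born layer beneath the cortical plate, 7 of 9 had higher values with a mean of 0.12 (camera adjusted p = 0.0376, 0.465 with an estimated correlation, exact permutation p = 0.0571). No member of either list passed in limma over all genes or adjusted over the list alone, and 1 of each had an unadjusted p under 0.05. In the excitatory list that was Lmo3, with lower values (-0.34 ± 0.12), beside Zfpm2 (0.38 ± 0.21) and the corticofugal neuron factor Fezf2 (0.23 ± 0.13). In the subplate list it was the channel subunit Kcnab1 (0.24 ± 0.10, and 0.06 after normexp background correction with a limma unadjusted p = 0.488), beside Nxph4 (0.17 ± 0.11; SE). Markers of Cajal-Retzius cells, the early marginal zone neurons, were not called (adjusted p = 0.376), with a mean of 0.03, a median of -0.01, Reln at 0.44 ± 0.30 and Ebf3 at 0.15 ± 0.13. None of its 16 members passed in limma by either adjustment, and 0 had an unadjusted p under 0.05. Both calls were lost with slide as a block (adjusted p = 0.0698 each), held within slide 1 (0.0284 each) and not within slide 2 (0.408 excitatory, 0.452 subplate). The excitatory call was also lost without control 3 (0.119), control 4 (0.263), mutant 1 (0.134), mutant 2 (0.0768) or mutant 4 (0.29), and the subplate call without control 1 (0.117), control 3 (0.19), control 4 (0.077), mutant 3 (0.131) or mutant 4 (0.214), while Cajal-Retzius markers were called higher without mutant 1 (0.00542).

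**Figure D2:**
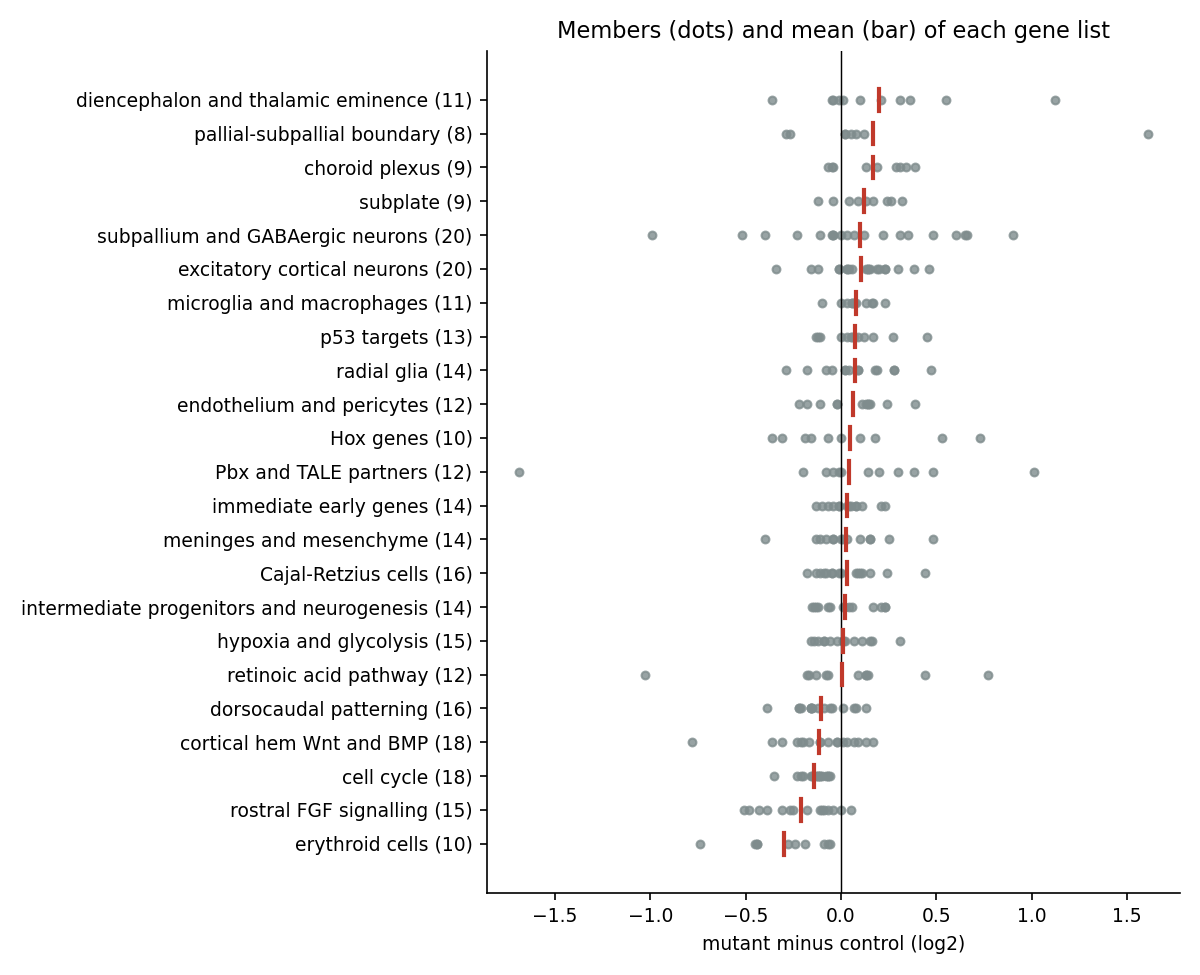
Mutant minus control difference (log2, horizontal axis) of every measured member (grey dots) and the mean (red bar) of each gene list but the sex-linked one, with the number of members measured in parentheses. All 18 cell cycle genes and all 10 erythroid genes lie below 0, and Pbx1 at -1.69 and Pknox1 at 1.01 are the extremes of the Pbx and TALE list.

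Lists of cortical patterning genes were not called in the comparison without covariates. In the rostral FGF list, whose ligands Fgf8 and Fgf17 come from the rostral midline, 14 of 15 members had lower values with a mean of -0.21 (camera adjusted p = 0.187), including Etv4 (-0.39 ± 0.34) and Etv5 (-0.31 ± 0.24; SE). That mean rested on mutant 1, whose list level was -1.17 against 0.14 to 0.34 in the other mutants, and without mutant 1 the list was called higher (adjusted p = 0.013). It was called higher within slide 1 (2.45e-05), lower within slide 2 (0.000368) and lower without mutant 3 (0.0156), and it was not called with slide as a block (0.318). With Xist as a covariate the mean was -0.36 and the list was called lower (0.00462), as with Xist and slide together (0.0178, mean -0.35). Dorsocaudal patterning genes (12 of 16 lower, mean -0.11, adjusted p = 0.297) included Npas3 (-0.39 ± 0.30) and Lef1 (-0.22 ± 0.21). Genes of the cortical hem, a medial source of Wnt and BMP signals (12 of 18 lower, mean -0.12, adjusted p = 0.286), included Msx2 (-0.36 ± 0.21) and Wnt3a (-0.31 ± 0.20). Both lists were called lower without mutant 3 (0.0292 dorsocaudal, 0.000569 hem), and the hem list was called lower within slide 1 (1.38e-07) and higher within slide 2 (0.00871). No member of these 3 lists passed in limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05.

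At the pallial-subpallial boundary, Dbx1, a homeobox gene of the ventral pallium, had a 3.05-fold higher mean level in mutants (0.94 ± 0.32 against -0.67 ± 1.09 in controls, SD, n = 4 each), with all 4 above all controls. The difference of 1.61 ± 0.50 (SE) did not pass over all genes or over the list alone (limma adjusted p = 1 and 0.0925). Sfrp2, a secreted Wnt antagonist of the same region, differed by -0.29 ± 0.11, and the 8 genes as a list were not called (camera adjusted p = 0.56, mean 0.17). In the retinoic acid pathway list the catabolic enzyme Cyp26a1 differed by -1.03 ± 0.29 and the synthetic enzyme Aldh1a3 by 0.77 ± 0.27 (SE), and by -0.34 and 0.18 after normexp background correction. The 12 genes had a mean of 0.00, a median of 0.01 and a camera direction of lower (adjusted p = 0.907). None of the 12 passed in limma over all genes or adjusted over the list alone, and 2 in each of these lists had an unadjusted p under 0.05.

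Markers of neighbouring tissues differed more between single cortices than between the groups. The subpallium and GABAergic neuron list (20 genes, mean 0.10, camera adjusted p = 0.186) ranged from -0.87 in control 3 to 0.90 in control 1, with Gad1 at 0.90 ± 0.55 and Arx at 0.22 ± 0.10 (SE). The diencephalon and thalamic eminence list (11 genes, mean 0.20, adjusted p = 0.366) stood at 1.45 in control 1 and between -0.73 and -0.46 in the other controls. Its members Irx5 and Foxb1 differed by 0.36 ± 0.31 and 1.12 ± 1.59 between the groups, and Foxb1 was well above background in only 3 of 4 controls. The choroid plexus list (9 genes, mean 0.16, adjusted p = 0.186) ranged from -0.55 in mutant 4 to 0.60 in mutant 1, with Sostdc1 at 0.31 ± 0.24 and Cldn1 at 0.29 ± 0.27. The subpallium list was called higher without control 1 (0.00725), without mutant 1 (0.00227) and within slide 1 (0.0356), the diencephalon list without control 1 (0.000654) and within slide 2 (1.71e-05), and the choroid plexus list without mutant 4 (0.000439), within slide 2 (0.00168) and with Xist as a covariate (0.049). With slide as a block the 3 adjusted p-values were 0.235, 0.429 and 0.292. No member of the 3 lists passed in limma over all genes or adjusted over the list alone, and 1 (Arx) had an unadjusted p under 0.05.

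**Figure D3:**
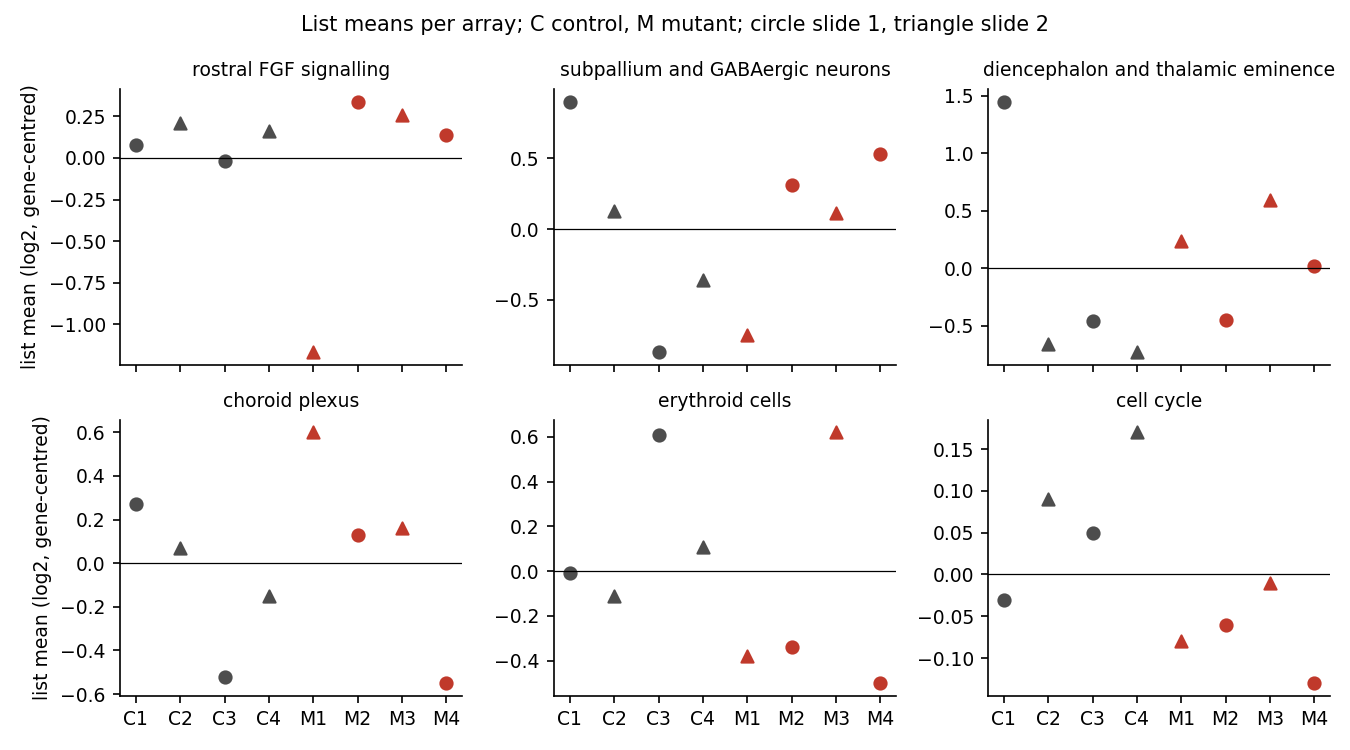
Mean of each gene list per array (log2, each gene centred over the 8 arrays) for 6 lists; grey is control, red is mutant, circles are slide 1 and triangles slide 2. Mutant 1 stands at -1.17 for the rostral FGF list and control 1 at 1.45 for the diencephalon list. For the cell cycle list the 4 mutants lie between -0.13 and -0.01, and control 1 at -0.03 lies within that range.

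Erythroid genes had lower values in mutants for all 10 measured members, by -0.30 on average. The list was called lower (camera adjusted p = 0.0376), and the call was lost with an estimated correlation (adjusted p = 0.724), with an exact permutation p of 0.4 for the list level. Rhag and Slc4a1, membrane proteins of red cells, differed by -0.74 ± 0.54 and -0.44 ± 0.28 (SE). None of the 10 passed in limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The list's level was 0.61 in control 3 and 0.62 in mutant 3, and at most 0.11 in the other 6 arrays. The call was lost without control 3 (0.592), control 4 (0.077), mutant 1 (0.0569), mutant 2 (0.219) or mutant 4 (0.29), and with slide as a block (0.0841), and the direction was lower within slide 1 (1.38e-07) and higher within slide 2 (0.408).

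Other non-neural cell types were not called by camera. Endothelium and pericyte genes (12 genes, mean 0.06, adjusted p = 0.376) included Rgs5 (0.39 ± 0.23) and Pecam1 (-0.18 ± 0.10). Meninges and mesenchyme genes (14 genes, mean 0.03, median 0.00, adjusted p = 0.831) included Prrx1 (-0.40 ± 0.19) and Foxc2 (0.25 ± 0.22; SE). Microglia and macrophage genes had higher values for 9 of 11 members (mean 0.08, adjusted p = 0.121), with Aif1 at 0.17 ± 0.12 and C1qc at 0.16 ± 0.13, and the list was called higher without control 2 (0.0178) or mutant 2 (0.000698). No member of these 3 lists passed in limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05.

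The remaining lists were not called either in the comparison without covariates. Hox genes, of which 10 of 29 were measured, had a mean of 0.05, a median of -0.03 and a camera direction of higher (adjusted p = 0.831), with Hoxb7 at 0.53 ± 0.34 and Hoxd8 at 0.73 ± 0.55, each well above background on 1 control and 3 mutant arrays. After normexp background correction these differences were 0.01 and -0.01. Immediate early genes (14 genes, mean 0.03, adjusted p = 0.376) included Egr2 (0.21 ± 0.16) and Jun (-0.13 ± 0.15). Hypoxia and glycolysis genes (15 genes, mean 0.01, adjusted p = 0.848) included Adm (0.31 ± 0.24) and Ankrd37 (0.15 ± 0.14; SE). In the p53 target list 10 of 13 members had higher values (mean 0.07, adjusted p = 0.177, and called higher after normexp background correction, 0.0351), with Trp53inp1 at 0.27 ± 0.09 as the only one with an unadjusted p under 0.05 and Plk2 at 0.45 ± 0.27. The X-inactivation transcript Xist was well above background in 2 controls (1 and 4) and 1 mutant (1), and the Y-linked genes Ddx3y and Eif2s3y in the other 5 arrays. The sexes were therefore not balanced between the groups (sex-linked list mean 1.95, adjusted p = 0.193; Ddx3y 2.82 ± 3.66, Eif2s3y 2.55 ± 3.56), and the list was called higher without control 2 (0.046), without mutant 1 (0.000791) and within slide 1 (0.0284). No member of these 5 lists passed in limma over all genes or adjusted over the list alone, and 0 members of the lists other than p53 targets had an unadjusted p under 0.05.

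Genes near the targeted loci were counted because, in a mixed strain background, alleles linked to Pbx1 or Emx1 go with the genotype. Of 280 named genes within 10 Mb of either locus 1 changed, Pbx1 itself, against 0 of 14459 elsewhere (Fisher's exact test p = 0.019; limma calls). With both loci left out the count was 0 of 278 (p = 1, exact). At an unadjusted p under 0.05 there were 7 of those 278 genes (2.52%) and 342 of the 14459 elsewhere (2.37%; Fisher's exact test p = 0.841).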

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

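The tests of a failed array and of a mislabelled control were chosen after the values of mutant 1 were seen. In 172 sets of 4 values, 12 arrays lay far from the other 3, of which 5 were mutant 1. Each set was a named gene, a list or the percent of probes well above background in 1 group. The 5 include Ddx3y, Eif2s3y and the sex-linked list, since mutant 1 was the only mutant with Xist well above background. The sets are therefore not independent of each other. Chance gives an array far from the other 3 in about 1 of 20 sets, or 9 here.

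Mutant 1 stood apart in the rostral FGF list, at -1.17 against 0.14 to 0.34 in the other mutants. It had the lowest of 8 values for 13 of the 15 genes, with Fgf8 at -3.01, Fgf17 at -7.55, Etv1 at -0.53 and Sp8 at -0.60. A failed array is argued against, since 2 of the other lists lay more than 0.5 (log2) below the other mutants, the subpallium list and the sex-linked list. A control carrying a mutant's label is argued against by Pbx1, which lay 0.10 above the mean of the other mutants. A dissection with less rostral midline tissue may account for the pattern and stays open. A separate list of 7 measured midline and septum genes was at -0.46 in mutant 1, below all 3 other mutants (-0.22 to 0.33). The gap of -0.24 is smaller than their range of 0.55. Control 3 was at -0.39 for that list with a rostral FGF level of -0.02, so a low midline level also occurred without the FGF pattern. An effect of Pbx1 loss that varies between embryos cannot be told apart from such a dissection with 1 embryo.

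Several single genes had a mutant array far from the other 3. Pknox1 was 1.2 in mutant 3 against 1.46 to 1.51 in the other mutants, still above all controls. Msx2 was -0.99 in mutant 3 against -1.68 to -1.60. Gucy1b2 was -2.43 in mutant 4 against -2.68 to -2.67, and Spaca1 was -4.00 in mutant 4 against -3.74 to -3.71. Cyp26a1 was -7.48 in mutant 2 against -8.15 to -8.07.

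Among the lists, the diencephalon and thalamic eminence level of control 1 was 1.45 against -0.73 to -0.46 in the other controls. The erythroid level of mutant 3 was 0.62 against -0.50 to -0.34. The p53 target level of mutant 1 was -0.10 against 0.07 to 0.09. Ddx3y and Eif2s3y both stood at -10.34 in mutant 1, not well above background, and the sex-linked list at -5.99, against 3.28 to 3.33 in the other mutants, which carried Y-linked signal.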

How the results depend on the processing

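Slide block with trended and robust eBayes, position block, slide block with Xist, and the neighbour count at an unadjusted p were chosen after the data had been seen, and the other settings were planned. For Pbx1 the difference stayed between -1.87 and -1.54 under all settings that kept all 8 arrays or 1 slide, and between -1.81 and -1.62 with 1 array left out, where the call was lost in 7 of 8 sets, so its adjusted p depended on the setting while its direction did not. Values below are log2 differences for genes and camera adjusted p-values for lists, and the cause of a lost call or turned direction was not tested except that a slide alone has 4 arrays and the unfiltered set more genes. Normexp gave 7 lists, with calls gained for Pbx and TALE partners (0.027), radial glia (0.0447) and p53 targets (0.0351), and the direction turned for Foxb1 (-0.06), Hoxd8 (-0.01) and the Hox list (0.242). Of the 61 named genes, 13 kept their direction with a difference more than 1.5 times smaller under normexp: Cyp26a1 (-0.34), Aldh1a3 (0.18), Nol9 (-0.50), Slc16a14 (-0.45), Spaca1 (0.30), Kcnab1 (0.06), Hoxb7 (0.01), Npas3 (-0.14), Irx5 (0.08), Aif1 (0.10), Egr2 (0.05), Ddx3y (1.52) and Eif2s3y (1.48). Quantile normalization gave 0 genes (limma, 695 at an unadjusted p under 0.05) and 2 lists, with Pbx1 at -1.68 (adjusted p = 0.0738), excitatory neurons and subplate at 0.0938 each, and the meninges list turned (0.944). Median scaling left subplate at 0.0617. Without a filter 0 genes passed (742 unadjusted), with Pbx1 at -1.69 (adjusted p = 0.0771), erythroid cells at 0.0578 and the retinoic acid list turned (0.84), and with the filter on all 8 arrays the Hox list turned (0.581). The mean of a gene's probes gave 2 lists, with excitatory neurons at 0.108, erythroid cells at 0.0986 and Pbx2 turned (-0.08). Slide as a block gave 2 genes (1092 unadjusted) and 1 list, with excitatory neurons and subplate at 0.0698 each, erythroid cells at 0.0841 and the Hox list turned (0.968), and with trended and robust eBayes added it gave the same counts (2 genes, 1 list) and list values (0.0698, 0.0698, 0.0841 and 0.968). Within slide 1, 0 genes (758 unadjusted) and 7 lists were called, with Pbx1 at -1.84 and the cell cycle list at 0.0532. Turned there were Pbx2 (-0.02), Etv5 (0.02), Etv4 (0.16), Irx5 (-0.27), Foxb1 (-1.51), Cldn1 (-0.18), Foxc2 (-0.19), Egr2 (-0.02), Jun (0.11) and the lists rostral FGF (2.45e-05), diencephalon (0.402), choroid plexus (0.488), meninges (0.542) and hypoxia (0.7). Within slide 2, 0 genes (753 unadjusted) were called, with Pbx1 at -1.54, excitatory neurons at 0.408 and subplate at 0.452. Turned there were Hoxd8 (-0.33) and the lists erythroid cells (0.408), cortical hem (0.00871), intermediate progenitors (0.562), retinoic acid (0.901) and sex-linked markers (0.947). Trended and robust eBayes and array weights each gave 2 genes, Pbx1 and Pknox1, with Pbx2 at -0.02 under array weights. Xist as a covariate gave 0 genes (876 unadjusted) and 5 lists, with calls gained for rostral FGF (0.00462, mean difference -0.36) and choroid plexus (0.049), Pbx1 at -1.64 (adjusted p = 0.0823), Pbx2 at -0.02, subplate at 0.0624 and retinoic acid turned (0.958), and with slide as a block too it gave 0 genes (1582 unadjusted) and 4 lists, with rostral FGF called (0.0178), Pbx1 at -1.63 (adjusted p = 0.0503), Pbx2 at -0.03, subplate at 0.1 and hypoxia turned (0.926). The deposited value table gave 0 genes (627 unadjusted) and 2 lists, with Pbx1 at -1.71 (adjusted p = 0.0804), excitatory neurons at 0.0625, subplate at 0.104 and meninges turned (0.974). Position as a block gave 0 genes (572 unadjusted), with Pbx1 at -1.69, subplate at 0.0694 and retinoic acid turned (0.994). Samples of the same number did not deviate together (correlations across genes of -0.07, -0.29, -0.10 and -0.27, and 0 of 8 samples correlated best with their own number), so the numbers do not pair them, and the replicate block gave 0 genes (693 unadjusted), with Pbx1 at -1.69, subplate at 0.0804 and retinoic acid turned (0.967). Treat gave 0 genes (137 unadjusted), and an estimated correlation gave 0 lists (1 unadjusted), with excitatory neurons at 0.643, subplate at 0.465, erythroid cells at 0.724 and cell cycle at 0.465. For genes near the loci Fisher's exact test gave p = 1 with the loci left out and 0.841 at an unadjusted p. With 1 array left out 0 to 1 genes and 1 to 7 lists were called (without mutant 2 the gene was AK043729, chosen here after its value was seen), and the lists ranged from 3.7e-07 to 0.0289 for cell cycle, 0.000314 to 0.29 for excitatory neurons, 0.00837 to 0.214 for subplate and 1.16e-07 to 0.592 for erythroid cells. Those with a direction that turned in such a set were Pbx2 (-0.09 to 0.06) and the lists rostral FGF (0.013 to 0.739), intermediate progenitors (0.131 to 0.987), choroid plexus (0.000439 to 0.954), meninges (0.0807 to 1), endothelium (0.152 to 0.78), retinoic acid (0.403 to 0.984), Hox (0.569 to 0.954), immediate early (0.154 to 0.974) and hypoxia (0.219 to 0.989). Of all other comparisons with the main values, 1476 of the named genes' and 519 of the lists' kept direction and side of the threshold. Signal over background limits dim genes such as Hoxb7 and Hoxd8, which were above background on 1 control array each.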

Other observations

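All genes and array patterns in the next 2 paragraphs were picked after their values were seen, as were the tests of slide, of a second probe, of progenitor number, of S phase, of Xist on the cell cycle list and of the splits within slides. The splits over all arrays and the scaling and Xist tests of the Pknox genes were planned.

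Several genes outside the fixed lists had large differences that did not pass over all genes in limma. Nt5e, the ectoenzyme that makes adenosine, had a 4.51-fold lower level in all 4 mutants (-2.17 ± 0.52, SE, unadjusted p = 0.00296). Alk, a receptor tyrosine kinase, differed by 0.89 ± 0.20 and was higher in all 4 mutants (0.00203). The steroid enzymes Hsd3b6 and Hsd3b2 differed by -1.96 ± 0.44 and -2.0 ± 0.76, each below all controls in 3 of 4 mutants, and as near-identical paralogs they are uncertain as separate genes. The 2 probes of Trp53 disagreed, with -0.84 ± 0.17 (unadjusted p = 0.0011) on one and -0.09 ± 0.31 on the other.

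Control 1 carried high levels of diencephalic genes, with Olig3 5.48, Gbx2 4.13, Irx1 2.87 and Tcf7l2 1.22 above the mean of the other controls, and it was the highest of 8 arrays for 6 of the 11 genes of that list. Foxb1 was at -1.66 in control 1 and at -8.07 and -6.56 in controls 2 and 3, and it was not well above background in control 4. Olig3 was also at -1.56 in mutant 3 and -3.10 in mutant 4, against -6.68 in mutant 2. The ventral genes Gsx2 and Isl1 were lowest in mutant 1, where neither was well above background, against -3.88 to -2.73 and -4.34 to -3.61 in the other mutants. Dlx2 was at 0.04 in mutant 4 and -3.38 in mutant 1.

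Chance cannot be excluded for any of the 3 counts set against other splits of the 8 arrays. Of the 35 splits into 4 and 4, 12 called at least as many genes as the 1 of the real split, and the highest other was 4612 genes, from the split that follows the slide, which points to the slides as the main structure of the samples. With slide as a block 2 genes passed. At least 4 lists, the real number, were called by 22 of the 35 splits, with 10 in the highest other, and 2 of 35 gave the cell cycle list a camera p as small as the real 1.28e-06, with 3.67e-07 as the smallest other. The real split is included in each of these numbers, and the 35 splits ignore the slide. Only 18 of them keep 2 arrays of each slide on each side, too few for a share under 0.05, and among these 7 called at least 1 gene (highest other 31), 16 at least 4 lists (10) and 2 gave the cell cycle list as small a camera p. With slide as a block in those 18, 3 called at least the 2 genes of the real split (highest other 112), all 18 at least its 1 list (9), and 2 gave a camera p of the cell cycle list as small as its 8.85e-08 (4.7e-08).

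Pknox1 and Pknox2 had higher values in all 4 mutants while Pbx1 fell, and neither passed over all genes (limma adjusted p = 0.13 for Pknox1). Each slide held 2 controls and 2 mutants, so a difference between slides falls on both groups alike. The within-slide differences (smallest 0.36) add no test of slide, since all 4 mutants lay above all controls. Background correction and scaling are argued against by the smallest difference under 4 other scalings (0.33). Both groups held arrays with and without Xist signal, and all 4 mutants lay above all controls, which argues against the uneven sexes. The smallest difference with Xist as a covariate (0.36) adds no further test of sex. Cross-hybridisation or a strain variant under the probe stays open, since 0 further probes of either gene were above background. No test here bears on whether the higher Pknox values follow from the loss of Pbx1. The partners Meis1 (0.14 ± 0.31), Meis2 (0.30 ± 0.12, limma unadjusted p = 0.0402) and Meis3 (-0.01 ± 0.16, SE) gave no call.

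The lower cell cycle list was present within both slides, with -0.11 as the mean difference nearest to 0. Slide was balanced between the groups, so these values add no further test of it. With Xist as a covariate the mean difference was -0.14 (camera adjusted p = 0.000156 at the preset correlation). That mean argues against the uneven sexes as the cause of the lower values. The call itself was lost with an estimated correlation (camera adjusted p = 0.465) and within slide 1 alone (0.0532). Fewer progenitors per cortex would give lower radial glia values, and 10 of the 14 members had higher ones. Their median difference was 0.06, above the cell cycle median of -0.13 by 0.19. That gap is less than the SD of 0.20 between the radial glia members, the limit set for this test. This SD is a spread between genes and not the error of the gap. In mutants the radial glia level lay at 0.01 to 0.07 and the cell cycle level at -0.13 to -0.01. In controls they lay at -0.08 to 0.06 and at -0.03 to 0.17. The lower cell cycle values came without lower radial glia values, which argues against fewer progenitors for these 14 genes. The radial glia list had a direction of higher (exact permutation p = 0.114, camera adjusted p = 0.187). Fewer cells in S phase stays open. Of 25 histone genes 17 had lower values with a mean of -0.09 (camera p = 0.331 with an estimated correlation). H2ac4 (-0.59) and H1f5 (-0.54), seen before the test, were left out. How well the RNA amplification captured histone transcripts is not known here, so these values decide neither way. A change of cell cycle activity in mutants is a hypothesis only, since 2 of 35 splits, the real one and 1 other, gave as small a p.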
